A study of Mus musculus with 2 samples.

How the data were processed

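Sorted tdTomato-positive lung cells of 2 mouse libraries, aWT and aKO, were measured by single-cell RNA sequencing, with groups taken from the sample titles. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized. They were made with Cell Ranger 7.2.0 against mm10, per the submitters' processing notes. Libraries followed the single-cell 3' v3 chemistry, per the labels' protocols. The annotation release and whether intronic reads were counted are not given in the sources used here. Both matrices list the same 32286 features, including an added tdTomato sequence. Symbols shared by more than 1 identifier (38 symbols) were kept apart by identifier, and in lists the identifier with the larger count was used, so near-identical copies such as Ccl21a are uncertain. Gene spans and coordinates came from GENCODE M21 on the same build and were found for 32158 features.

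Barcodes with at least 500 genes and at most 15% mitochondrial counts were kept. Scrublet, run per library through scanpy 1.11.5, called 702 aWT (4.39%) and 400 aKO barcodes (3.62%) as doublets, which were removed, against loading rates of 12.8% and 8.82%. This left 14957 and 10385 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 components were taken, and cells were clustered with leidenalg 0.10.2 at resolution 1 on 15 neighbours, without integration. Endothelial-like cells were clustered again in the same way, giving 18 clusters. Other tools were Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

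Clusters were named from marker lists fixed before the data were examined. A class needed 3 markers in 20% of a cluster's cells, and a subclass 3 markers that were also 2-fold over the other cells. A cluster stayed unnamed when its 10 leading genes by fold held more markers of another class than of its own, or when its UMI count was low and none of its own markers led. How markers were combined into a name was set after the clusters had been seen. The rule left 4 clusters unnamed, with 1.99% of aWT and 14.8% of aKO cells. In 84.9% of cells the cluster held at least 90% cells of 1 library, so a cluster may stand for a library and not a type.

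Counts were summed over the cells of each class and library and divided by the library's class total to give CPM. Log2 ratios are aKO over aWT after adding 5 CPM to each, which understates the change of low genes. Counts by size used a minimum of 50 CPM in 1 library and a 2-fold ratio. The 34 gene lists, fixed before the data were examined, used members with at least 5 CPM, counted as higher or lower at 1.5-fold, and a median's percentile among 10000 random lists matched on mean CPM in 20 bins. Genes named were the 12 highest and 12 lowest with the same sign in each subclass of at least 100 cells per library (leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes), up to 4 per list by size, 3 each way per subclass, and Acvrl1 and Eng. Other genes were named as markers or as library checks, and Ackr3, Fos, Egr1, Emcn, Flt1 and Nrp1 after their values had been seen. No test between groups was possible with 1 library per group. CPM have exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, for counting error only. Shares of cells with a UMI were compared after thinning to 2000 UMIs per cell, which left out 2315 aWT and 1440 aKO cells.

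The size rule was tested on simulated data. For aKO against aWT endothelial-like cells, 200 of 4215 genes were changed: 50 of 50 genes made 3-fold higher, 50 of 50 made 4-fold higher, 50 of 50 made 3-fold lower and 49 of 50 made 4-fold lower were recovered, and 0 unchanged genes passed. The simulation holds counting error alone.

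Alternatives fixed beforehand were TMM factors from edgeR 4.0.16, the mean over cells, equal subclass weights, general capillary cells alone, doublet calls kept or removed at 0.8% per 1000 cells, a stricter and a looser cell filter, another pseudocount, thinning, other minimum CPM, other resolutions, centring on each library, separate clustering and a definition by endothelial UMIs. Leaving out lymphatic clusters, removing the trend with gene span, putting unnamed clusters back, together or cluster 6 alone, leaving out endothelial-like clusters of low depth that no marker led, and clustering without genes that differed were added after the data had been seen.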

Results

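The series profiled single cells from mouse lung in which VE-cadherin-cre, a recombinase driven by an endothelial cadherin promoter, switched on the red fluorescent protein tdTomato. Fluorescent cells were sorted and sequenced by the 10x Genomics 3' method, which reads the 3' ends of transcripts and counts each molecule once through its unique molecular identifier (UMI). The series title places the animals in a model of hereditary hemorrhagic telangiectasia 2, the vascular disorder tied to ACVRL1, which encodes the endothelial BMP receptor ALK1. There were 2 libraries from C57BL/6J mice aged 10 to 12 weeks, 1 labelled aWT and 1 labelled aKO. The deposited matrices held 15996 barcodes and 72270260 UMIs for aWT, and 11045 barcodes and 75950364 UMIs for aKO. After filtering, 14957 aWT cells (median 3922 UMIs) and 10385 aKO cells (median 5738 UMIs) remained. With 1 library per group there was no replicate error, so no difference between the groups was tested below. Intervals of CPM and shares cover counting error only, and bootstrap intervals cover the spread over members of a list.

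The first question was what the library labels correspond to at the receptor gene. Acvrl1 (ENSMUSG00000000530, chromosome 15, 101128522 to 101145336, plus strand, mm10) stood at 1028 CPM (UMI counts of the gene scaled to the total of the class in its library; 95% Poisson interval 1020 to 1036) in aWT endothelial-like cells and at 489 CPM (484 to 495) in aKO, a log2 ratio of -1.06. It was lower in aKO in each of 5 endothelial subclasses, with log2 ratios of -0.76 in general capillary, -0.80 in aerocyte capillary, -0.43 in arterial, -0.40 in venous and -0.85 in lymphatic cells. With the subclasses weighted equally the Acvrl1 log2 ratio was -0.66. General capillary identity genes also had a median below 0 in each subclass, at -1.01 in lymphatic cells. The lymphatic Acvrl1 ratio is therefore not read as a change within those cells. The labels name no deleted gene or exon, and 3' reads need not fall in a deleted part, so the remaining Acvrl1 counts do not check the labels. Eng (chromosome 2, 32646595 to 32682669), which encodes the ALK1 co-receptor endoglin, stood at 1077 CPM in aWT and 463 CPM in aKO.

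The next comparison asked how the endothelial-like cells of the libraries differed in genes that answer to BMP9 and ALK1. Of 15 measured members of that list, 12 were at least 1.5-fold lower in aKO and 1 at least 1.5-fold higher, and the list's median log2 ratio of -1.61 lay below the medians of all 10000 random lists matched on expression. Id1 and Id3, inhibitors of basic helix-loop-helix factors and direct BMP targets, stood at 1198 and 983 CPM in aWT and at 122 and 144 CPM in aKO, with log2 ratios of -3.24 and -2.73. Smad6 and Smad7, inhibitory SMADs that BMP signalling induces, had log2 ratios of -2.61 and -2.53. The receptor gene Bmpr2 was at 2370 CPM in aWT and 677 CPM in aKO, and Hey1, a Notch and BMP target, had a log2 ratio of -2.14. Ackr3, a scavenging chemokine receptor, was the member that lay higher, at 220 CPM in aWT and 628 CPM in aKO; it was singled out after its value had been seen. Of the 21 immediate early and heat shock genes of the stress list, which dissociation can induce, 8 were at least 1.5-fold lower and 13 lay within 1.5-fold (median -0.53). Within single subclasses more of them were lower, from 11 of 21 in general capillary to 13 of 21 in arterial cells. The subclass medians ran from -0.80 in arterial to -0.61 in aerocyte cells.

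The median of the response list was below 0 in each subclass, at -1.68 in general capillary, -1.51 in aerocyte capillary, -1.58 in arterial, -1.35 in venous and -0.40 in lymphatic cells. In general capillary cells Id3 was at 984 CPM in aWT and 18.1 CPM in aKO (log2 ratio -5.42), and Id1 at 1239 and 32.5 CPM (-5.05). In lymphatic cells Id1 and Id3 had log2 ratios of -0.02 and 0.36, while Smad6 and Smad7 had -3.19 and -2.40. In the same lymphatic cells the general capillary identity list had a median of -1.01 (9 of 12 lower). The Smad6 and Smad7 ratios are therefore not read as a change within lymphatic cells. The general capillary list was also lower in venous (-1.80, 10 of 12 lower), arterial (-1.16, 9 lower and 1 higher) and aerocyte cells (-0.68, 6 lower). The response medians in these subclasses carry the same limit. Nrp1 was at 95 CPM in aWT and 6.18 CPM in aKO lymphatic cells, and Flt1 at 189 and 33.0 CPM; these 2 genes were singled out after their values had been seen. After each cell was thinned to 2000 UMIs, 79.3% of aWT and 12.4% of aKO endothelial-like cells held an Id1 UMI (85.7% and 27.5% before thinning). Thinning left out 2125 aWT and 532 aKO endothelial-like cells, whose full sets had median depths of 3924 and 6370 UMIs. Among 103 aWT alveolar type 2-like cells (median 15819 UMIs before thinning), the thinned share was 12.6% (6.90 to 20.6%), and 2 of 16 in aKO (median 16012 UMIs before thinning) held an Id1 UMI. In general capillary cells (median 3521 and 5554 UMIs) the thinned share was 81.5% in aWT and 5.26% in aKO (4.49 to 6.12%). Before thinning the shares were 86.6% and 12.5%. No Id1 expression is read from the aKO share in that class. The aWT alveolar type 2-like share comes from the other library and 16 aKO cells are few, so neither sets a background level for aKO. In aKO lymphatic cells the thinned share was 20.03% (18.1 to 22.1%), so the aKO shares differed between subclasses and were not background as a whole.

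**Figure D1:**
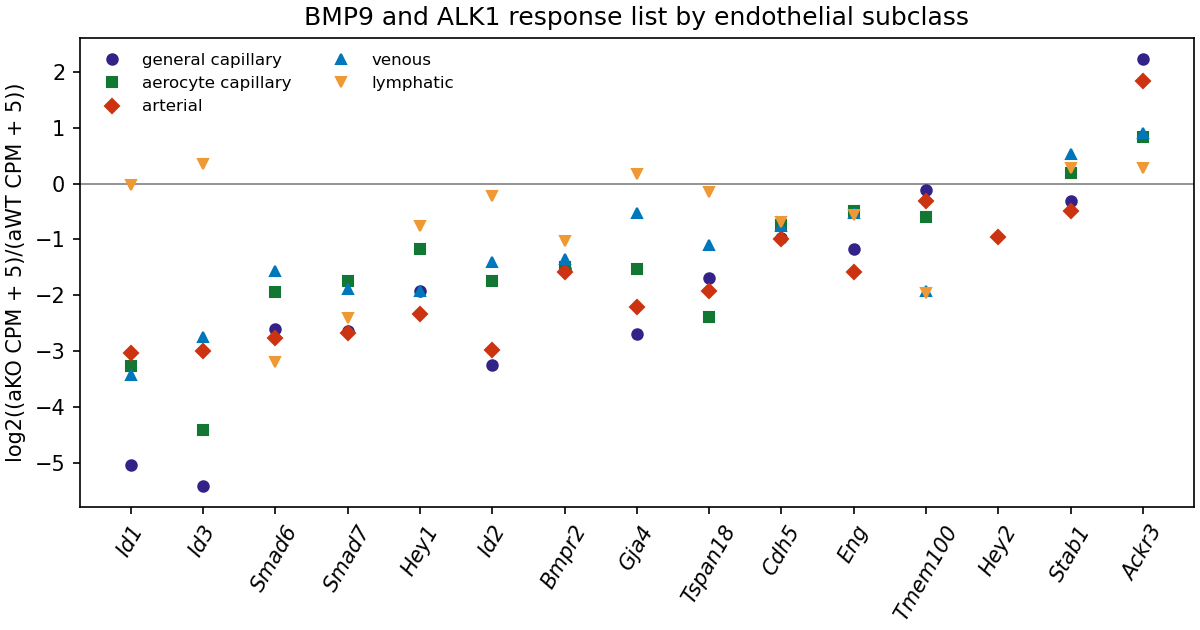
Log2 ratio of aKO over aWT CPM (vertical axis, with 5 CPM added) for each measured gene of the BMP9 and ALK1 response list (horizontal axis), with 1 point per endothelial subclass. Id3 lies at -5.42 in general capillary cells and at 0.36 in lymphatic cells, while Smad6 lies below 0 in each subclass. General capillary genes (not shown) also lay lower in lymphatic cells, so the Smad6 point there is not read as a lymphatic change. Those genes lay lower in venous, arterial and aerocyte cells too, so the points of these subclasses carry the same limit.

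Across all genes of endothelial-like cells, 4590 reached 50 CPM in 1 of the libraries. By the fixed rule of size, 235 of them were at least 2-fold higher in aKO and 159 at least 2-fold lower. These are counts by size and not by a test. With each subclass weighted equally, 89 were higher and 110 lower, so the higher share of these genes went from 59.6% to 44.7%. Of 4487 genes eligible for naming, 2026 had the same sign in all 5 subclasses (45.2%). The subclasses come from the same pair of libraries, so these signs are not independent of each other.

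Of the 12 genes highest in aKO with the same sign in each subclass, St6galnac5, a sialyltransferase gene (chromosome 3, 152817081 to 152982246), was at 3.73 CPM in aWT and 190 CPM in aKO, with log2 ratios of 6.63 in general capillary and 3.82 in aerocyte cells. Ifi27l2b and Ifi27l2a, interferon-inducible genes, had log2 ratios of 4.12 and 3.26 and were highest in arterial cells, at 5.10 and 4.67. Lcn2, an iron-carrier binding protein of inflammation, was at 17.3 and 267 CPM (3.61). Lgals1 (3.16), Arsj (3.15), D5Ertd615e (2.76), S100a6 (2.64), Trp53i11 (2.51), 2200002D01Rik (2.46), Cda (2.43) and Clca3a1 (2.36) completed the group. Several of these ratios were smaller within general capillary cells, at 0.21 for 2200002D01Rik, 0.41 for Ifi27l2b, 0.74 for Lcn2, 0.97 for S100a6, 1.03 for Clca3a1, 1.22 for Lgals1 and 1.46 for Ifi27l2a. With equal subclass weights D5Ertd615e stood at 0.98, Cda at 1.09, Trp53i11 at 1.69 and Lcn2 at 1.91. In lymphatic cells Ifi27l2b (0.014), Trp53i11 (0.021), D5Ertd615e (0.18), 2200002D01Rik (0.23) and Cda (0.27) differed by less than 1.5-fold. The same held in aerocyte cells for 2200002D01Rik (0.18), Ifi27l2a (0.23), S100a6 (0.48), Ifi27l2b (0.52), Lgals1 (0.58) and Clca3a1 (0.58). Of the 12 lowest, Esm1, a tip cell gene that VEGF induces, was at 57.4 CPM in aWT and 2.73 CPM in aKO (-3.01). Vegfa was at 302 and 44.3 CPM (-2.64). The others beside Id1, Smad6 and Smad7 were 4930444A19Rik (-2.95), Gm20631 (-2.67), Olfm2 (-2.64, but -1.24 in general capillary and -0.40 in venous cells), Casc4 (-2.62), Ankrd44 (-2.56) and AY036118 (-2.45), which overlaps ribosomal RNA sequence. 4930444A19Rik and Gm20631 were also leading genes of cluster 4 of all cells, an endothelial-like cluster of 1407 aWT and 10 aKO cells with a median of 1461 UMIs in aWT. Without it and cluster 14, another such low-depth cluster (367 aWT and 5 aKO cells), their log2 ratios were -2.73 and -2.46. Both genes also led cluster 4 of the endothelial-like cells (1798 aWT and 8 aKO cells, median 3244.5 UMIs in aWT). That cluster was not left out as a whole, so its part in these ratios was not settled. Sftpc, a surfactant gene of alveolar type 2 cells, had the lowest ratio (-3.79); it was at 135700 CPM in the 105 aWT alveolar type 2-like cells, a class with 17 cells in aKO, and at 153 CPM in aWT endothelial-like cells.

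Genes that mark general capillary cells were lower in aKO, as were the ligand genes Cxcl12 and Bmp6. Of 12 measured general capillary identity genes, 11 were lower (median -1.24, below all random lists), among them Glp1r (-2.01), Sema3c (-1.86), Itga1 (-1.82) and Kit (-1.75). The same list served to name general capillary cells, whose share differed between the libraries as clustered. Its percentile is therefore not read as a change within those cells. Within general capillary cells alone the list median was -0.94. It was -1.80 in venous, -1.16 in arterial, -1.01 in lymphatic and -0.68 in aerocyte cells, so it was not lowest in its own class. Cxcl12, a chemokine gene, had a log2 ratio of -2.30 and the ligand gene Bmp6 one of -2.03 in endothelial-like cells. The aerocyte identity median was -0.47 (7 of 14 lower, percentile 0.03), but 0.10 with equal subclass weights and -0.06 in aerocyte cells. Arterial identity genes went both ways, with a median of -0.19 (6 of 15 lower and 4 higher), and in arterial cells the median was -0.79 (9 lower and 2 higher). In general capillary cells the arterial median was -1.07 (8 of 13 lower, 1 higher), and in venous cells -0.39 (3 of 13 lower, 5 higher). The aerocyte and arterial lists also served to name those subclasses. The pan-endothelial list had a median of -0.37 (7 of 16 lower, 1 higher), inside the middle 95% of random lists (-0.40 to 0.44). Emcn, named after its value had been seen, was the member higher, at 0.68, or 0.15 within general capillary cells. Calcrl stood at -1.47, Epas1 at -1.31 and Cdh5 at -1.24.

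All 6 measured MHC class II genes were lower in aKO (median -1.67, below all random lists), led by Cd74 (-2.34), H2-Aa (-2.01) and H2-Ab1 (-1.98). That median was -1.61 in general capillary cells but -0.18 in lymphatic cells, where 1 of 4 was lower. The MHC class I median was -0.45 (5 of 14 lower, percentile 0.02), although H2-D1 was higher at 0.71. In general capillary cells the class I median was -0.16, with 1 of 14 lower, and in arterial cells 0.02. It was -0.40 in venous (5 of 14 lower, 1 higher), -0.26 in lymphatic and -0.25 in aerocyte cells. The interferon response median was -0.35 (3 of 20 lower, 1 higher), with Ifi44 at -1.01 and Iigp1 at -0.99, and Ifi27l2a in the opposite direction. Within general capillary cells the interferon median was 0.09. In venous cells it was -0.53 (8 of 20 lower, 2 higher), in aerocyte and lymphatic cells -0.19, and in arterial cells -0.16. In the immediate early and dissociation stress list 8 of 21 genes were lower and 0 higher (median -0.53), among them Hspa1a (-2.03), Hspa1b (-1.89) and Hspb1 (-1.43). The immediate early genes Fos (0.09) and Egr1 (0.50), singled out after their values had been seen, lay within 1.5-fold. In general capillary cells 11 of the 21 were lower and 1 higher, with Fos at -1.34 and Egr1 at 0.58.

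Other lists lay higher in aKO endothelial-like cells. The lymphatic identity list had a median of 1.86 (11 of 11 higher), but 0.20 within lymphatic cells (2 of 11 higher). Within general capillary cells it was 0.55 over 5 measured members, 2 of them higher. The same list served to name lymphatic cells, whose share differed between the libraries. The proliferation list had 18 of 23 higher (median 1.08), and a median of 0.22 over 7 measured members within general capillary cells (1 higher). Its median was 0.70 in venous cells (7 of 11 higher), 0.37 in lymphatic, 0.11 in arterial and 0.08 in aerocyte cells. The basement membrane list had 12 of 20 higher (median 0.78), led by Lama4 at 2.22, and a median of 0.04 within general capillary cells. In venous cells the median was 0.79 (12 of 20 higher), and it was 0.16 in aerocyte, 0.15 in arterial and 0.04 in lymphatic cells. The mesenchymal transition list had 10 of 16 higher (median 0.82), against 0.01 in general capillary and 1.20 in venous cells, where the matrix genes Fn1 and Col3a1 had log2 ratios of 3.20 and 3.07. In lymphatic cells both lay lower in aKO, at -2.28 and -3.82, and with equal subclass weights Fn1 stood at -0.023. Nuclear oxidative phosphorylation genes had a median of 0.65 (11 of 20 higher) and stayed above 0 in each subclass, from 0.29 in aerocyte to 0.80 in venous cells; shorter genes as a whole lay higher in aKO (Spearman's rho -0.32 and Pearson's r -0.22 between span and log2 ratio across 4485 genes, which are not independent replicates). Coagulation genes had a median of 0.66 (8 of 14 higher), with S100a10 at 1.78, against 0.24 in general capillary (3 of 10 higher) and 0.05 in aerocyte cells. In venous cells the coagulation median was 0.47 (7 of 14 higher, 1 lower). The progenitor list had a median of 0.78 (4 of 7 higher), with the surface sialomucin gene Cd34 at 1.61 and, in general capillary cells, at 2.92; the list median was 0.59 in general capillary and -0.32 in lymphatic cells.

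Sprouting genes went both ways in all endothelial-like cells together (median -0.06, 6 of 19 higher and 8 lower). The semaphorin receptor gene Nrp2 stood at 1.66, or -0.20 within general capillary cells, and the VEGF receptor gene Kdr at -1.03. By subclass the list median was -0.77 in arterial (10 of 17 lower, 3 higher), -0.25 in lymphatic, -0.20 in general capillary, -0.12 in venous and 0.04 in aerocyte cells. Notch signalling had a median of -0.10, with the ligand gene Dll1 at 1.55. Medians were 0.43 for venous identity, 0.39 for lipid handling, 0.29 for hypoxia and glycolysis, 0.21 for BMP and TGF-beta components, 0.21 for vasoactive genes, 0.19 for osteogenic genes, 0.18 for flow response, 0.16 for junctions and 0.16 for inflammation. They were -0.03 for the unfolded protein response, -0.16 for p53 and cell cycle arrest, -0.24 for mitochondrially encoded genes, 0.50 for the 3 measured pericyte and smooth muscle genes and -0.72 for the alveolar epithelial list. Within general capillary cells the median was -0.45 for venous identity (6 of 12 lower), -0.29 for lipid handling, -0.11 for flow response, 0.03 for hypoxia and glycolysis, 0.11 for Notch signalling and 0.16 for aerocyte identity. The median of BMP and TGF-beta components was -0.33 in arterial (8 of 23 lower, 4 higher) and -0.28 in lymphatic cells (7 of 23 lower, 1 higher). It was -0.0015 in general capillary, -0.07 in aerocyte and 0.07 in venous cells, and -0.062 with equal subclass weights. In the haemoglobin list 1 gene was measured, so no median was taken. In the sex-linked list 2 genes were higher and 4 lower (median -3.48); Xist was at 3.53 CPM in aWT and 719 CPM in aKO, so sex and group were confounded in every comparison.

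**Figure D2:**
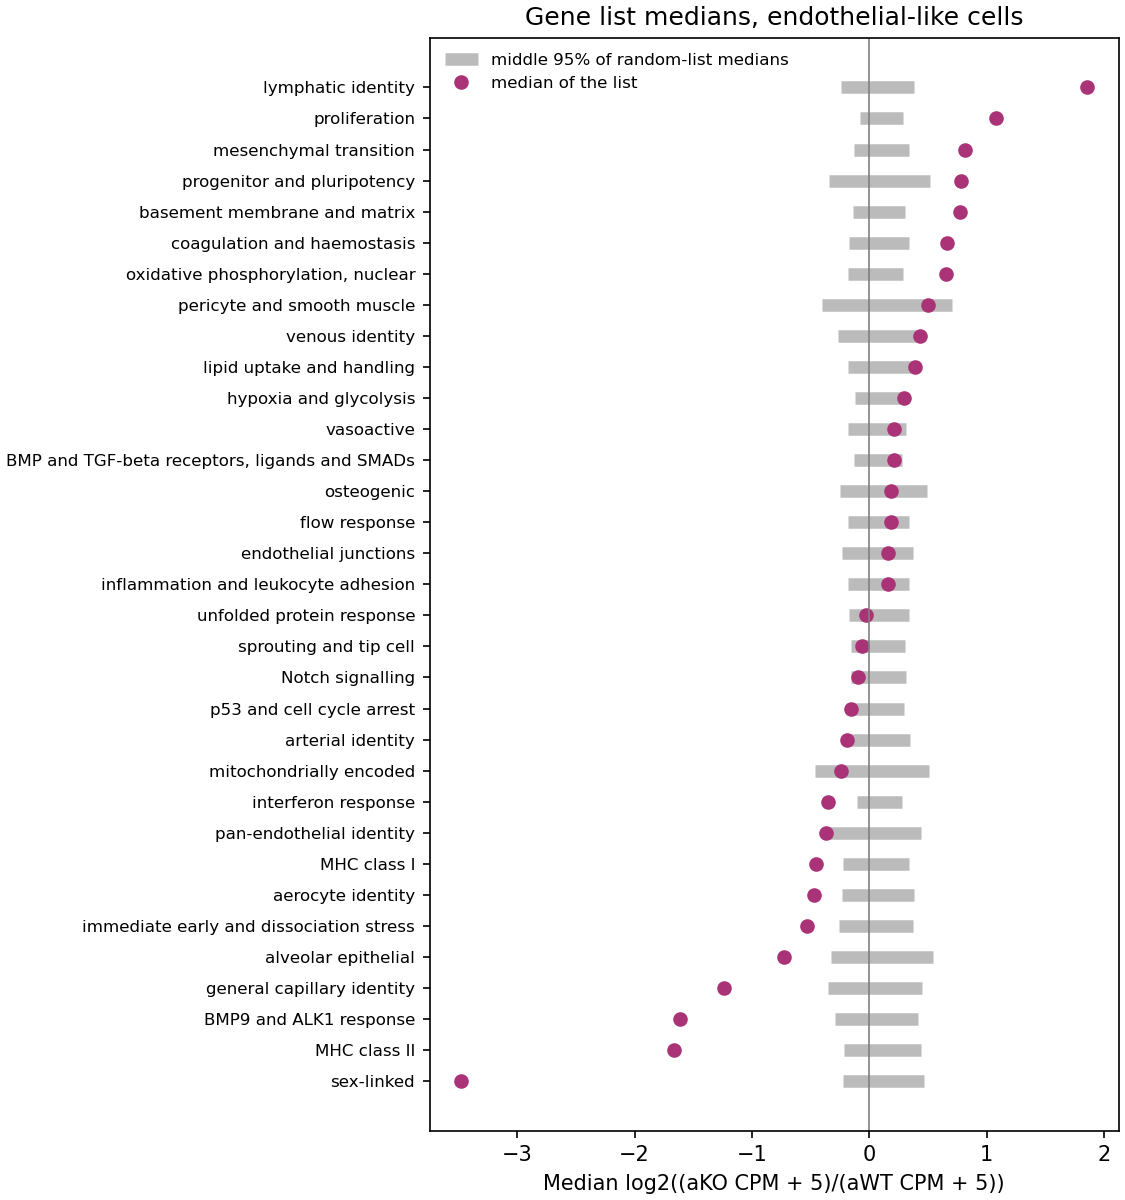
Median log2 ratio of aKO over aWT in endothelial-like cells (horizontal axis) for each gene list (vertical axis), as points, with the middle 95% of medians of random expression-matched lists as grey bars. The BMP9 and ALK1 response list lies at -1.61 and the lymphatic identity list at 1.86, both outside their bars; the sex-linked list lies lowest at -3.48.

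The 3 highest and 3 lowest genes of each subclass overlapped in part. Sftpc recurred among the lowest in general capillary, aerocyte and venous cells, Id3 in general capillary and aerocyte cells, and Id1 in general capillary and venous cells. Among the highest, Sema5a recurred in general capillary cells (1.85 CPM in aWT and 78.4 CPM in aKO) and aerocyte cells (3.46 and 193 CPM), as did St6galnac5, and Ifi27l2b recurred in arterial and venous cells. Other genes stood among them in 1 subclass. In aerocyte cells, Alpl was at 180 CPM in aWT and 1.68 CPM in aKO, and the hyaluronan receptor gene Lyve1 at 82.3 and 972 CPM. In arterial cells, Esm1 (-4.53), Olfm2 (-4.23) and Slc45a4 (-3.75) were lowest. In venous cells, Cadm1 was at 414 and 41.3 CPM, and Col8a1 at 1.67 and 93.4 CPM. In lymphatic cells, Lsamp was at 195 and 0.772 CPM and Gap43 at 8.54 and 86.4 CPM.

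The sort was described by the makeup of the cells. Clusters named endothelial-like held 96.9% of aWT cells (95% Clopper-Pearson interval 96.6 to 97.2%) and 85.0% of aKO cells (84.3 to 85.7%). The direction of this gap depended on the naming rule. Cluster 6 of all cells, with 1359 aKO and 2 aWT cells, stayed unnamed because 2 of its 10 leading genes were the haemoglobin genes Hbb-bs and Hba-a1 and 1 was endothelial, yet Hbb-bs UMIs lay in 6 of its 1361 cells and Pecam1 UMIs in 1182. Its aKO cells had a median of 1649 UMIs and a median mitochondrial share of 0.339%, against 5738 UMIs and 1.67% over all kept aKO cells. Unnamed clusters held 1.99% of aWT and 14.8% of aKO cells; with cluster 6 alone put back, the endothelial-like shares were 96.9% in aWT and 98.1% in aKO. With all 4 put back they were 98.9% and 99.8%, although Dcn, Col1a1 and Msln were among the leading genes of cluster 15, and S100a8 and S100a9 among those of cluster 23. Alveolar type 2-like cells made up 0.702% of aWT and 0.164% of aKO cells, and airway epithelial-like cells 0.435% and 0.0578%. After thinning, 20.2% of aWT and 15.2% of aKO endothelial-like cells held a tdTomato UMI (34.9% and 40.0% before), against 1 of 103 aWT alveolar type 2-like cells.

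Lymphatic cells, marked by Prox1 and Ccl21a, made up 4.02% of aWT endothelial-like cells (3.71 to 4.36%) and 19.9% of aKO (19.1 to 20.8%), mostly in clusters 7 and 11 of the endothelial-like cells in both libraries, with the rest chiefly in clusters 16 and 17. The clusters given with the shares hold most of each subclass, not all of it. With each library clustered on its own the lymphatic shares were 3.83% and 9.41%. Cells of unnamed clusters were left out of all these shares, among them cluster 6 of all cells (1359 aKO and 2 aWT cells). The low-depth clusters 4 and 14 of all cells (1407 and 367 aWT cells) stayed in. At resolution 0.5 only 1.68% of aKO cells stayed unnamed. General capillary cells then made up 44.9% of aWT and 43.8% of aKO, and lymphatic cells 3.81% and 17.2%. Arterial cells made up 10.1% of aWT (clusters 8 and 12) and 19.9% of aKO (clusters 6 and 12 of the endothelial-like cells), or 14.8% and 18.3% with doublet calls kept. Aerocyte capillary cells, the large gas-exchange capillary cells, made up 17.1% of aWT (clusters 3 and 13) and 11.8% of aKO (cluster 10). Venous cells made up 10.8% of aWT (cluster 5) and 11.2% of aKO (cluster 9); the ratio of 1.03 lay between 0.761 and 1.10 over the clustering, doublet and cell filter settings, on both sides of 1, so no direction is read. Proliferating cells numbered 23 in aWT (0.159%) and 136 in aKO (1.54%), with median depths of 10270 and 16559 UMIs, so doublets among them were not excluded. General capillary cells made up 57.8% of aWT (clusters 0, 2 and 4) and 35.7% of aKO (cluster 1), but 37.9% and 40.9% with each library clustered on its own. There 20.3% of aWT and 0.368% of aKO endothelial-like cells had no subclass name, so no direction is read from these shares. Over the 9 alternatives the aWT share lay between 35.3% and 50.3%, below 57.8% in each. Between 8.36% and 20.3% of aWT endothelial-like cells had no subclass name in them, against 0.0949% to 6.35% of aKO. Clustered without the genes that differed 2-fold, the ratio of aKO over aWT shares was 5.59 for lymphatic and 1.70 for arterial cells. The sort gate can set such shares, and so can the difference in depth, which was examined for lymphatic cells alone: of cells thinned to 2000 UMIs, 4.76% in aWT and 19.2% in aKO held at least 2 UMIs of Prox1, Mmrn1, Reln and Flt4.

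**Figure D3:**
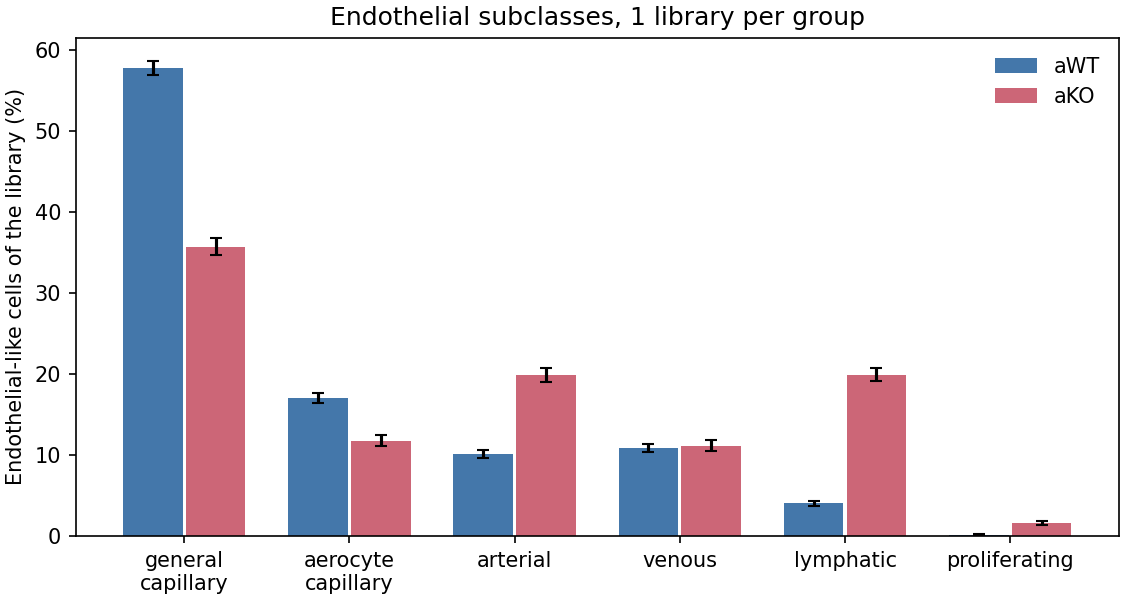
Share of each library's endothelial-like cells (vertical axis, percent) in each endothelial subclass (horizontal axis), with bars for aWT and aKO and error bars for 95% Clopper-Pearson intervals that cover counting error only. Lymphatic cells stand at 4.02% in aWT and 19.9% in aKO. The general capillary difference depends on the clustering, and its aWT share was lower than plotted, at 35.3% to 50.3%, in each alternative. Cells of unnamed clusters, 1.99% of aWT and 14.8% of aKO cells, are left out.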

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

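The tests of dissociation stress and of lymphatic cell number, the clustering without genes that differed, the removal of the trend with gene span and the return of unnamed clusters were chosen after results had been seen.

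Of aKO cells, 13.1% lay in unnamed cluster 6 of all cells, against 0.0134% of aWT cells, a signal in cells outside the comparisons; there Pecam1 stood at 1830 CPM and Id1 at 19.7 CPM, with a median of 1649 UMIs and a median mitochondrial share of 0.339%, against 1.67% over all kept aKO cells. A further 0.770% of aKO cells lay in unnamed cluster 18, against 0.287% of aWT cells. Xist, the X-inactivation RNA, stood at 719 CPM in aKO endothelial-like cells and 3.53 CPM in aWT, while the Y-linked genes Ddx3y and Uty stood at 107 and 126 CPM in aWT and at 0.0302 and 0.0604 CPM in aKO. The sex of the animals was therefore confounded with the group.

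BMP9 and ALK1 response genes were lower in aKO endothelial-like cells, with a median log2 ratio of -1.61. A trend with gene length did not account for this, since the median was -1.74 (bootstrap over members -2.41 to -1.09) once that trend was removed. General capillary cells alone gave -1.68 (-2.63 to -0.88), which argues against the number of lymphatic cells as the whole of it. Dissociation stress stayed open: the stress list lay 1.08 above the response list (0.41 to 1.97), but of the subclasses this held beyond its interval in arterial cells alone (0.78, 0.10 to 1.90), and in lymphatic cells the difference was -0.21 (-1.001 to 0.416). Lower ALK1 signalling may underlie the pattern as a hypothesis, with sex and preparation also open and untested.

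The lymphatic share was larger in aKO under each clustering, doublet and cell filter setting run. Clustering choice left a lowest ratio of shares of 2.46 over 9 alternatives (highest 5.59), reached with each library clustered on its own, where 24.0% of aKO cells stayed unnamed. Depth left a ratio of 4.02 (3.56 to 4.55) for cells thinned to 2000 UMIs with at least 2 UMIs of Prox1, Mmrn1, Reln and Flt4. Recovery of cells in dissociation, the sort gate, sex and genotype stayed open and untested.

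In 84.9% of cells the cluster held at least 90% cells of 1 library. This share was 78.6% without sex-linked genes (78.5 to 78.7% over 5 seeds), 85.5% with each gene centred per library (85.3 to 85.5%) and 85.7% with cells thinned (85.7 to 85.8%). Sex-linked transcripts themselves, left out alone, and depth, evened out alone, were thus not the whole of it. They were not removed together. Centring used each library's own means although the makeup of cells differed, so it cannot settle a constant shift per gene. Other effects of sex, the preparation and genotype stayed open and untested.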

How the results depend on the processing

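Leaving out lymphatic clusters, removing the gene span trend, putting unnamed clusters back, leaving out low-depth clusters and clustering without genes that differed were chosen after the data had been seen. No paired analysis was possible because each group had 1 library. The cause of the changes below was not tested. The lower BMP9 and ALK1 response median and the lower Acvrl1 level kept their direction under all 13 alternatives, and the larger lymphatic, arterial and proliferating shares in aKO under all 9.

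Genes higher in aKO numbered 89 with equal subclass weights, where 75 of the 235 remained. With a minimum of 10 CPM there were 498 higher and 248 lower, and with no minimum 527 and 260, since more genes could pass. Lists with medians of at least 1.5-fold numbered 12, and 7 both with equal weights and in general capillary cells. The response median was -1.70 by the mean over cells, -1.46 with equal weights, -1.68 in general capillary cells, -1.69 with 1 CPM added, -1.72 thinned, -1.80 without lymphatic clusters, -1.67 without low-depth clusters (where 216 genes were higher and 152 lower) and -1.74 less the span trend. The Acvrl1 log2 ratio was -1.10 with TMM factors, -0.99 by the mean over cells, -0.66 with equal weights, -0.76 in general capillary cells, -1.03 thinned, -0.86 without lymphatic clusters and -1.18 less the span trend.

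Among values of at least 1.5-fold, the log2 ratio was reversed in general capillary cells for Acta2 (-0.10), Bmp4 (-0.41), Fabp4 (-0.29), Lamb1 (-0.10), Nrp2 (-0.20), Pparg (-0.026), Runx2 (-0.42), Serpine2 (-0.14) and Vcam1 (-0.0083). With equal weights it was reversed for Fn1 (-0.023), Gja1 (-0.013) and Runx2 (-0.49), and without lymphatic clusters for Pparg (-0.32) and Runx2 (-0.30). A gene value or list median moved when it lay outside a 95% interval from Poisson resampling of the counts behind the reported value. Small shifts of genes with many counts therefore count as moved. Of the other named gene values, 1133 moved and 842 did not, and of list medians 224 moved and 192 did not. Of values under 1.5-fold as reported, 16 values of 6 genes (Egr1, Fos, Gucy1a1, Myh11, Notch2 and Spp1) and 23 medians of 12 lists changed sign. With members as measured in endothelial-like cells, general capillary cells alone gave -0.24 for venous identity, -0.028 for lipid handling, 0.096 for the interferon response and 0.075 for coagulation, which kept its sign, and equal weights gave -0.21 for osteogenic genes and 0.10 for aerocyte identity.

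Shares also moved. With doublet calls kept, aWT had 41.6% general capillary and 14.8% arterial cells; aKO had 97.7% endothelial-like, 42.0% general capillary, 10.7% aerocyte, 18.3% arterial, 9.39% venous and 18.2% lymphatic cells. With the highest doublet scores removed, aWT had 97.3% endothelial-like, 45.1% general capillary, 15.7% aerocyte, 8.18% arterial and 10.3% venous cells, and aKO had 86.4% endothelial-like, 17.0% arterial, 10.5% venous and 1.08% proliferating cells. With the stricter filter, aWT had 98.2% endothelial-like, 49.0% general capillary, 11.4% venous and 3.52% lymphatic cells, and aKO 89.98% endothelial-like cells. With the looser filter, aWT had 96.2% endothelial-like, 48.5% general capillary and 3.50% lymphatic cells, and aKO 21.4% arterial cells. At resolution 0.5, aWT had 44.9% general capillary and 14.1% arterial cells; aKO had 98.1% endothelial-like, 43.8% general capillary, 10.2% aerocyte, 17.8% arterial, 9.55% venous and 17.2% lymphatic cells. At resolution 2, aWT had 98.1% endothelial-like, 35.3% general capillary and 14.1% arterial cells, and aKO 32.2% general capillary and 22.3% arterial cells. With centring, aWT had 41.5% general capillary and aKO 21.0% arterial cells. With each library clustered on its own, aWT had 37.9% general capillary cells; aKO had 75.97% endothelial-like, 40.9% general capillary, 13.2% aerocyte, 22.4% arterial, 11.9% venous, 9.41% lymphatic and 1.84% proliferating cells. Without genes that differed, aWT had 95.9% endothelial-like, 50.3% general capillary, 9.06% venous and 3.53% lymphatic cells, and aKO 83.5% endothelial-like, 17.9% arterial and 6.89% venous cells. The endothelial-like share turned direction with all unnamed clusters put back (98.9% in aWT, 99.8% in aKO), with cluster 6 alone put back (96.9% and 98.1%), by endothelial UMIs after thinning (99.1% and 99.4%), at resolution 0.5 and with doublet calls kept. The ratio of venous shares, 1.03 as reported, fell below 1 in 7 of the 9 alternatives, to 0.761 without genes that differed. Depth limited low genes: by a limit of 3 counts, a count of 0 allowed up to 0.0479 CPM in aWT and 0.0453 CPM in aKO endothelial-like cells.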

Other observations

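The relation with gene span was examined after results had been seen, and no difference in this part was tested.

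The vasoactive list had 5 of 18 genes higher and 4 lower in aKO endothelial-like cells, with medians from -0.23 in lymphatic to 0.40 in arterial cells. Its member Edn1, which encodes the vasoconstrictor endothelin 1, had log2 ratios of -3.81 in general capillary, -1.40 in aerocyte, -2.04 in arterial, 0.80 in venous and -2.59 in lymphatic cells. Nos3, the endothelial nitric oxide synthase gene, had 1.23, 0.47, 1.54, 1.18 and -0.16 in the same order. Of the BMP and TGF-beta components, the ligand gene Bmp4 had -0.41, 0.69, -0.39, 2.59 and -1.75. Smad1, which carries BMP receptor signals, was at 105 CPM in aWT and 310 CPM in aKO endothelial-like cells, with log2 ratios of 2.07, 0.76, 1.63, 1.31 and -0.29 in that order.

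Short genes lay higher in aKO than long ones. Across 4485 genes, which are not independent replicates, Spearman's rho between gene span and log2 ratio was -0.32 and Pearson's r was -0.22. The median log2 ratio was 0.33 in the 20% of genes with the shortest spans and -0.13 in the 20% with the longest. Ribosomal protein genes took 4.45% of aWT and 7.31% of aKO endothelial-like UMIs, and Malat1, a nuclear RNA, took 3.98% and 2.58%.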
